A study of Drosophila melanogaster with 4 samples.

How the data were processed

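Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map histone H3 trimethylated at lysine 4 (H3K4me3) in whole larvae of the third larval instar (L3) of Drosophila melanogaster, strain Oregon-R, wild type. H3K4me3 is a histone mark known from the promoters of active genes. Per the labels, larvae were homogenised and fixed with formaldehyde, chromatin was sheared by sonication, and the mark was precipitated with lot 2 of a rabbit polyclonal antibody raised against a peptide of human H3 trimethylated at K4. The labels put 2 libraries in the ChIP group and 2 in the input group, each numbered replicate 1 and 2. Files of enriched regions were analysed for the 2 ChIP libraries and for the replicate set, called the combined list below. Files of the input libraries were not analysed here.

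Each file is a list of regions with a first and a last base, counted from 1, and a score. The authors deposited 1 list for each ChIP library and 1 combined list, all on FlyBase release 5, per the file headers. The submitters' processing notes name Bowtie version 0.12.7. The program that called the regions, its threshold, the part played by the input libraries and the way in which the replicates were combined are not given in the sources used here. The deposited score of each region has no stated scale or log base; it was between -0.18 and 5.24 in the combined list, and 20 regions there had a score below 0. Scores are the authors' own values and are used only to describe and rank regions within a list and, with that limit, to compare the same region between the 2 replicate lists. No read counts accompany the regions, so the sequencing depth behind a region is unknown and no interval based on reads is given. Poisson intervals on numbers of regions are two-sided, have a 95% level and cover counting error only.

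The gene table at hand gives positions on Release 6 of the genome and the regions are on release 5. Positions were not converted between builds, so regions are reported by position and no gene is assigned to them. The comparisons with transcription starts and with gene lists that had been planned before the data were examined were therefore not run.

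Everything else was computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A region of one list was called shared when it overlapped a region of the other list by at least 1 bp. Chance overlap came from 1000 circular shifts of the other list within each sequence, which keep widths and spacing, with a one-sided permutation test. Regions in only 1 replicate list were compared with shared regions by a two-sided permutation test of the difference of medians with 100000 resamples. Regions were treated as units in these tests, so the p-values describe the spread between regions of 1 library and not between animals or cultures. Nothing in the labels says that the replicates came from separate cultures. Matched regions are pairs in which each region overlapped exactly 1 region of the other list. Numbers of regions per Mb were compared between groups of sequences by an exact binomial test on the sequence lengths given in the file headers; regions are clustered along the arms, so these p-values are too small. Arms were also compared by permuting whole 1 Mb windows 10000 times. These tests between arms and the score comparisons by chromosome were chosen after the data had been seen; the overlap test and the test of regions in only 1 list were fixed before the data were examined.

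The regions to be named were fixed before the data were examined: the 5 widest and the 5 highest-scoring regions of the combined list, and the 5 widest regions found in only 1 replicate list. Other regions named were chosen after their values were seen. The overlap count, the shift test, the median test and the window test were tested on simulated region lists made from the 4213 regions of replicate 1 on the 5 large arms. All of the regions simulated as shared were found. These were real regions moved by less than their own width, so they had to overlap, and this checks the code only. Of 20 lists made by the same circular shifts that the test uses, 1 passed the shift test at 0.05. Such lists cannot show whether circular shifts are a fair picture of chance overlap. With 300 bp added to the widths on X, the window test gave a difference of 342 bp. Its permutation p of 0.002 was the smallest that the fewer permutations used in this check can give. Of 20 sets of shuffled widths, 0 passed the window test at 0.05. Widths were shuffled over single regions, so this check cannot show how the test behaves where neighbouring regions have similar widths. The alternatives tried were an overlap of at least 50% of both regions, only the regions above the median score of each list, merging of neighbours within 500 bp, only the 6 arms 2L, 2R, 3L, 3R, 4 and X, and each replicate list alone.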

Results

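H3K4me3 was mapped in L3 larvae of wild-type Oregon-R flies, with 2 ChIP libraries and 2 input libraries. The lists of enriched regions held 4332 regions for replicate 1, 4245 for replicate 2 and 4451 for the combined list. Per replicate this was 4289 ± 61.5 regions (SD, n = 2) covering 15.3 ± 0.0374 Mb (SD, n = 2). On the 6 chromosome arms 2L, 2R, 3L, 3R, 4 and X, the regions covered 12.6% ± 0.0368 of the sequence (SD, n = 2), and 13.3% in the combined list. The median width was 2848 ± 8.13 bp (SD, n = 2), with the widest region at 25365 bp in replicate 1 and 25631 bp in replicate 2. In the combined list the middle 50% of regions were between 2377 and 4210 bp wide, 742 regions exceeded 5 kb and 112 exceeded 10 kb. The depth of sequencing behind the lists is unknown.

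Regions with low scores tended to be narrower than regions with high scores. In the combined list 27.3% of regions had a score below 1, and in the replicates 22.1% ± 1.17 (SD, n = 2). A score of 1 need not mean the same in each list, so these shares are not directly comparable. Width rose gradually with score. Across the regions of the combined list, which are not independent replicates, Spearman's rho between width and score was 0.79 and Pearson's r was 0.55. The lowest-scoring 25% of regions had a median width of 1950 bp and none was wider than 5 kb, whereas the highest-scoring 25% had a median width of 4433 bp and 38.1% of them exceeded 5 kb.

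The replicates were compared to find which H3K4me3 regions were found in both libraries. Of the regions of replicate 1, 97.1% (4208 of 4332) overlapped a region of replicate 2, and 98.2% of the regions of replicate 2 (4167 of 4245) overlapped one of replicate 1. Circular shifts gave a mean overlap of 22.4% and 22.6%, with a maximum of 28.1% and 28.4%. The one-sided permutation p was 0.001 for each of the 2 directions, the smallest that 1000 shifts can give, and 0.001 after adjustment over both. The libraries shared 94.4% of the bases covered by either list. Boundaries of the 4059 matched regions differed by a median of 42 bp, taken as the mean of both ends. Across matched regions the scores had a Pearson's r of 0.99 and a Spearman's rho of 0.98; these values are across regions, which are not independent replicates.

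The regions found in only 1 replicate list were narrow and low-scoring. In replicate 1 these 124 regions had a median width of 1560 bp against 2887 bp for shared regions, and a median score of 0.31 against 2.28. In replicate 2 the 78 such regions had a median width of 1472 bp against 2885 bp, and a median score of 0.25 against 2.08. Each of these 4 differences had a permutation p of 1e-05, the smallest that 100000 resamples can give, and 1e-05 after adjustment over the 4 tests. The tests of width and score are not independent, since width rose with score. A wide region also overlaps another list more easily, so part of the width difference may come from the definition of a shared region. All 2166 regions of replicate 1 with a score above its median overlapped a region of replicate 2. In the other direction 2 of 2122 regions did not. These were the region of U from 7530982 to 7533102, with a score of 2.36, and the region of 2L from 21540085 to 21541656, with a score of 2.08. The former was also the widest region found only in replicate 2, at 2121 bp. It was followed by X from 10732575 to 10734653, with a score of 0.63, and by 2 regions of 3L that start at 14969527 and 9033858 and 1 of 2RHet that starts at 333267, with scores of 0.09, 0.23 and 0.31. The widest regions found only in replicate 1 were 3R from 26411511 to 26413530 at 2020 bp, with a score of 0.55, and 2L from 21479137 to 21481137 at 2001 bp, with a score of 1.47. The next were the regions that start at 20102042 and 18802393 on 3R and at 2805078 on 2L, with scores of 0.52, 0.49 and 0.47.

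The combined list was compared with the lists of the single libraries that it draws on, so it is not independent of them. It overlapped 4329 of the 4332 regions of replicate 1 and all 4245 of replicate 2. Of its 4451 regions, 4088 overlapped both replicate lists, 121 replicate 1 only, 76 replicate 2 only and 166 neither. The 166 regions had a median width of 1243 bp and a median score of 0.24, against 2988 bp and 2.13 for the regions found in both. Of the 166, 103 were narrower than 1304 bp, the width of the narrowest region in either replicate list. A region of the combined list joined several regions of replicate 1 in 117 cases and several of replicate 2 in 80 cases.

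The widest H3K4me3 domains were on chromosome arms 3R, 2R, 2L and X, and each was covered in both replicates. The widest region of the combined list was on 3R from 7033894 to 7065124, 31.2 kb long, with a score of 2.67. Each replicate split it into 3 regions, the widest being 14219 bp in replicate 1 and 14172 bp in replicate 2, which together covered 30759 and 31001 bp. The region of 2R from 10038144 to 10063766, 25.6 kb long, was a single region in each replicate, of 25365 and 25631 bp. The region of 2L from 4441476 to 4466690, 25.2 kb long, was split into 2 regions in each replicate. The region of X from 509000 to 532498, 23.5 kb long, was 1 region in replicate 1 and 2 regions in replicate 2. The region of 2L from 10418300 to 10440944, 22.6 kb long, was split into 3 regions in each replicate. Of the regions wider than 10 kb, 73 of 76 in replicate 1 overlapped one of that width in replicate 2, and 73 of 90 in the other direction. Of the 112 combined regions of that width, 72 overlapped one in both replicates.

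The highest scores lay outside the large arms in 4 of 5 cases. The 3 highest-scoring regions of the combined list were on U, the scaffold of sequence not placed on a chromosome. These were 7869404 to 7871760 with a score of 5.24, 5540918 to 5543350 with 4.02, and 6383826 to 6386654 with 3.73. All 3 were found in both replicates, with scores of 5.19 and 4.33, of 4.25 and 3.78, and of 4.08 and 3.37 in replicates 1 and 2. The fourth was on 2R from 4785712 to 4790956 with a score of 3.36, and with 3.47 and 3.31 in the replicates. The fifth was on chromosome 4 from 1349888 to 1351752, 105 bp from the end of the sequence, with a score of 3.32, and no region of either replicate list overlapped it. Regions of U were narrow, with a median width of 2162 bp. The input libraries were not analysed here and the score has no stated scale. Whether the high scores on U and at the end of chromosome 4 reflect the mark or the mapping of reads there was not tested.

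The sequences of the genome were compared to find where H3K4me3 regions lay. Chromosome 4, the small chromosome known for its heterochromatin, carried regions at a density like that of the large arms, and the heterochromatic scaffolds carried few. The density was 37.4 ± 0.523 regions per Mb on 4 (SD, n = 2), 31.7 ± 0.707 on 2L, 41.1 ± 0.134 on 2R, 33.9 ± 0.173 on 3L, 34.9 ± 0.811 on 3R and 34.0 ± 0.788 on X. In the combined list chromosome 4 had 56 regions, 41.4 per Mb with an interval from 31.3 to 53.8, and the ratio to the 5 large arms was 1.14 with an interval from 0.862 to 1.49. This difference did not pass the exact binomial test (p = 0.31, adjusted p = 0.31 over 5 density comparisons). The 6 scaffolds of heterochromatin together had 47 regions on 9.28 Mb, 5.06 per Mb against 36.3 on the 6 arms. The ratio was 0.139 with an interval from 0.102 to 0.186 (exact binomial adjusted p = 5.5e-83), and it was 0.131 in replicate 1 and 0.140 in replicate 2. Densities here and below divide by the full sequence lengths. How much of the scaffolds and of U could receive mapped reads is unknown, so a lower density there need not mean less of the mark.

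Among the heterochromatic scaffolds, XHet had 3 regions and YHet had 4, 14.7 and 11.5 per Mb, with intervals of 3.03 to 43.0 and 3.14 to 29.5. The 4 regions of YHet lay between 304444 and 329390, and all 4 were found in both replicates, with combined scores between 1.81 and 2.54. 2LHet had 2 regions, 2RHet 16, 3LHet 15 and 3RHet 7. The unplaced scaffold U had 34 regions on 10.0 Mb, 3.38 per Mb, a ratio of 0.0932 to the 6 arms (exact binomial adjusted p = 2.5e-104). Uextra, a further collection of unplaced sequence, had 0 regions on 29.0 Mb in each of the 3 lists, for which the one-sided 95% bound on counting error is 3 regions or 0.103 per Mb. Whether reads on Uextra were used in the calling is not given in the sources used here.

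**Figure D1:**
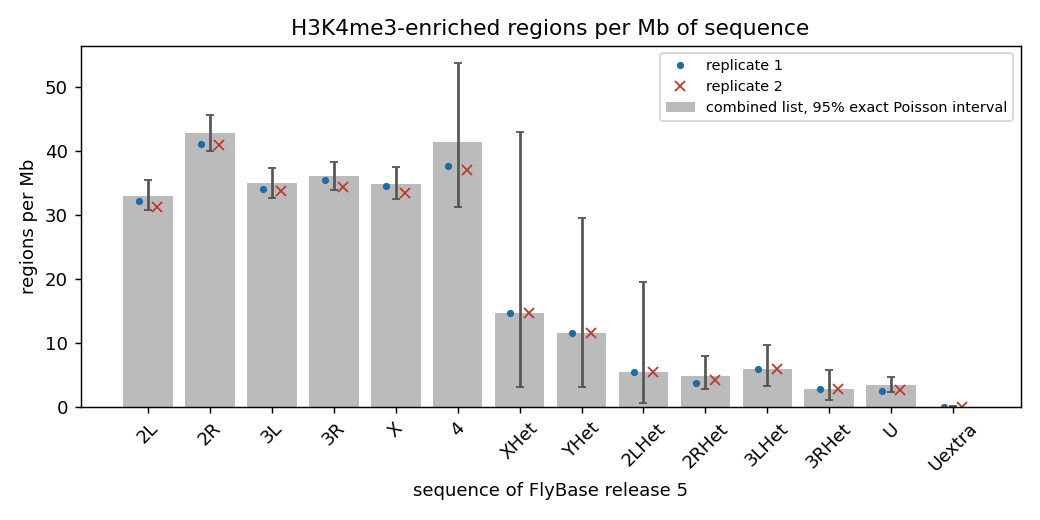
Regions per Mb (vertical axis) on each sequence of FlyBase release 5 (horizontal axis), with bars for the combined list, 95% exact Poisson intervals for counting error, and points and crosses for replicates 1 and 2. The combined density was 42.8 per Mb on 2R and 41.4 on chromosome 4, whereas the heterochromatic scaffolds lay between 2.78 and 14.7 per Mb and Uextra at 0.

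Arm 2R had the highest density of H3K4me3 regions among the large arms. Its 1 Mb windows held a mean of 43.0 regions against 35.1 on the other large arms. A permutation of the 117 windows, which compared the highest of the 5 arm means with its chance value, gave p = 0.003, and p = 0.013 and 0.003 in replicates 1 and 2. X was not shown to differ in density from the autosomal arms (a difference of -1.41 regions per window, permutation p = 0.596). The ratio of its density to theirs was 0.955, with an interval for counting error from 0.883 to 1.03. Regions on X were wider: the median was 3001 bp on X and 2827 bp on the 4 autosomal large arms, a difference of 174 bp in the combined list, 150 bp in replicate 1 and 181 bp in replicate 2. The permutation p over windows was 0.007, adjusted to 0.014 over the tests of width and score, and 0.024 and 0.012 in the replicates. X had the largest median of the 5 large arms, and these p-values take no account of a choice among arms. The autosomal arms also differed from each other. In replicates 1 and 2 the median was 2909.5 and 2944 bp on 3R, against 2969 and 3013 bp on X and 2755.5 and 2781 bp on 2L. In the combined list 3R was at 2849 bp and 2L at 2775 bp. The difference in median score, 2.12 on X against 2.03, did not pass the test in the combined list (permutation p = 0.078, adjusted p = 0.078), and had permutation p of 0.043 and 0.012 in replicates 1 and 2. Among regions above the median score the width difference was 205 bp with a permutation p of 0.083.

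Regions were spread unevenly along each arm. On the large arms the median gap between neighbours was 8.64 kb, 259 gaps were at most 500 bp long and 234 exceeded 100 kb. The longest stretches without a region were on 2L from 15772047 to 16250003 (478 kb) and from 16911345 to 17382553 (471 kb), and on 3L from 18179429 to 18613725 (434 kb). Each replicate list had the same 3 stretches as its longest, with nearly the same ends. The densest of the 236 windows of 500 kb was on 2L from 10000001 to 10500000, with 39 regions in the combined list and 40 and 39 in replicates 1 and 2. The median window held 18 regions.

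**Figure D2:**
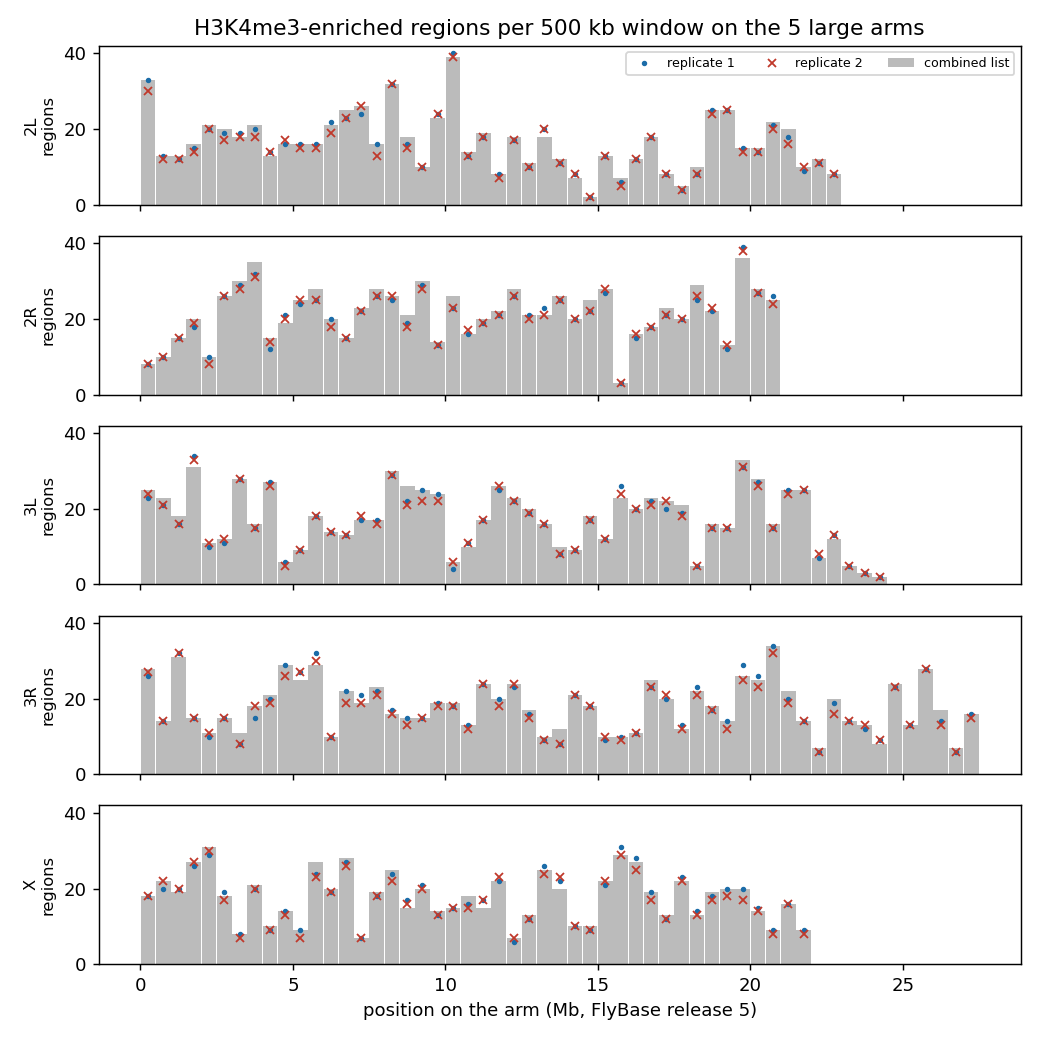
Number of H3K4me3 regions per 500 kb window (vertical axes) by position in Mb on each of the 5 large arms (horizontal axis), with grey bars for the combined list, blue points for replicate 1 and red crosses for replicate 2. Windows held between 2 and 39 regions in the combined list, and the density of 39 was reached on 2L at 10000001 to 10500000.

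Scores of matched regions were higher in replicate 1 than in replicate 2 on the large arms, and about equal on chromosome 4 and on the heterochromatic scaffolds taken as a group. On the large arms 3598 of 3942 matched regions (91.3%) had the higher score in replicate 1, with a median difference of 0.19. On chromosome 4 this held for 26 of 49 regions (53.1%), with a median difference of 0.01, and on the heterochromatic scaffolds for 23 of 43 regions (53.5%), with a median difference of 0.03. Among these scaffolds XHet, with 3 matched regions, had a median difference of 0.29 and YHet, with 4, of 0.08. On U it held for 17 of 25, with a median difference of 0.22. Among the 104 windows of 1 Mb on the large arms with at least 20 matched regions, the median difference ranged from 0.09 to 0.25 with an SD of 0.03, and chromosome 4 lay below all of them. Without that minimum, 1 of 121 windows was as low as chromosome 4. With 1 pair of libraries this describes these 2 libraries and has no further replicate check.

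**Figure D3:**
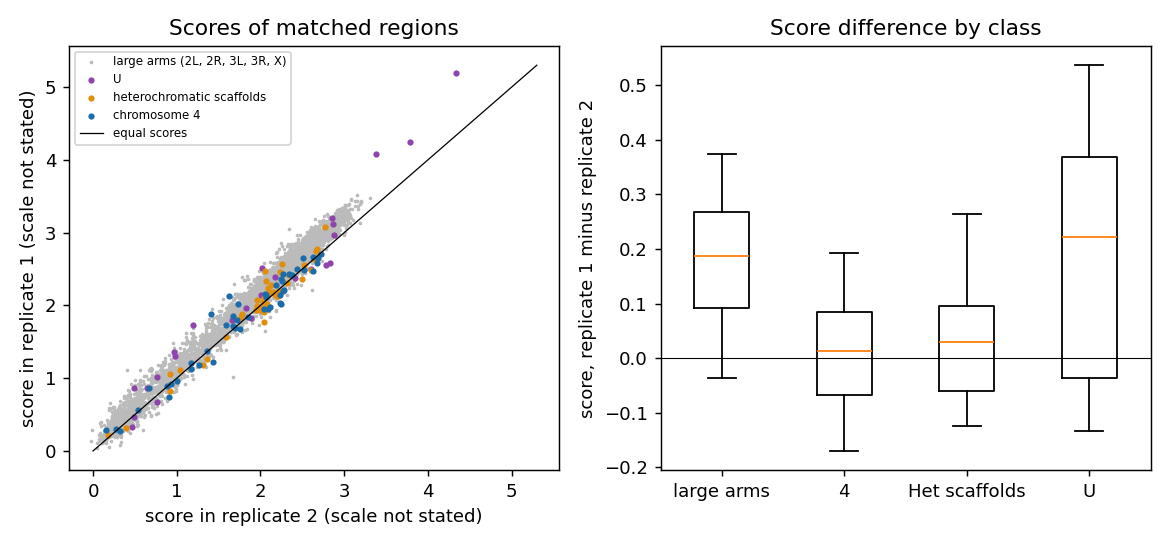
Left, the score of each matched region in replicate 1 (vertical axis) against replicate 2 (horizontal axis), on the authors' scale, with the line of equal scores. Right, the score in replicate 1 minus that in replicate 2, with boxes for the median and the middle 50% of regions and whiskers from the 5th to the 95th percentile. The median difference was 0.19 on the large arms, 0.01 on chromosome 4, 0.03 on the heterochromatic scaffolds and 0.22 on U.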

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

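The overlap of the replicates stayed far above chance under each of the 4 other settings, which were fixed before the data were examined, between 94.9% and 97.1% for replicate 1 and between 95.9% and 98.2% for replicate 2. Regions in only 1 list remained narrower and lower-scoring than shared ones when neighbours were merged and when only the 6 arms were used. Restricting that comparison to regions above the median score tests nothing, since all but 2 of them lay in the whole other list. The same restriction left 2166, 2122 and 2225 regions in replicate 1, replicate 2 and the combined list by its construction, and 8.71% of the 6 arms covered. The covered share of the 6 arms was 12.56% to 12.61% in the lists that leave out 1 replicate, below the 13.3% of the combined list. The width difference between X and the autosomes, 174 bp, was 205 bp among regions above the median score and no longer passed (permutation p = 0.083); the number of regions tested fell there, and whether that was the cause was not tested. The lower density on heterochromatic scaffolds, the higher density on 2R and the smaller score difference on chromosome 4 kept their direction and call in each alternative run. After each list was divided by its median the shortfall on chromosome 4 was -0.06 in units of that median. It is therefore not on the same scale as the -0.17 of the undivided scores. With division 2 of 117 windows were as low, and without it 0 of the same 117. All alternatives for the regions in only 1 list, for the comparisons between arms and for the scores were chosen after seeing the data. The comparisons with transcription starts and gene lists, with their alternatives, were not run, since the gene table is on another genome build. No paired analysis was possible because the input libraries that share replicate numbers with the ChIP libraries were not analysed here. Unknown depth limits every statement on weak regions: a region missing from a list may lie just under its threshold, and the low scores of the regions in only 1 list, at least 97.4% of them in the lowest-scoring 25%, do not decide this.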

Other observations

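The tests of why regions were in only 1 list, the test of an overall score shift on chromosome 4 and the 221 bp width difference on X after joining neighbours within 500 bp were chosen after the result was seen. For the other tests the deciding bounds were written before their values were computed, though after the lists had been looked through. The test of an overall score shift was first set up for all matched regions, with bounds on the large arms, and was narrowed to the large arms after chromosome 4 was seen to differ.

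H3K4me3 regions clustered along the large arms. Of 1189 windows of 100 kb, 159 (13.4%) held no region, against a median of 19 (1.60%) and a maximum of 34 in 1000 random placements of the same regions that kept widths and avoided overlap (one-sided permutation p = 0.001, the smallest they can give). Towards the centromere the density fell on 4 of the 5 large arms. The last 1 Mb held 20 regions on 2L, 18 on 2R, 6 on 3L and 17 on X, against 33.6, 44.0, 36.2 and 35.8 per Mb in the rest of these arms, but 42 on 3R against 35.9. Over the 5 arms the mean difference was -16.5 regions per Mb, with an exact two-sided sign-flip p of 0.1250, and 0.0625 is the smallest that 5 arms allow.

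Of the 166 combined regions that neither replicate list held, 12 had a score above 1. Among these, 5 were on U and 3 lay on chromosome 4 within 16.7 kb of the end of the sequence, starting at 1335112, 1347968 and 1349888 with scores of 2.20, 2.20 and 3.32. The 2 regions found only in replicate 2 with a score above the list's median, and the highest-scoring region found only in replicate 1, were on U and on 2L between 21479137 and 21541656.

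For the score difference between replicates, on the large arms at least 90.3% of matched regions were higher in replicate 1 on each arm, which restates the pattern. Over all matched regions the median difference rose with score, from 0.10 in the lowest-scoring 25% to 0.24 in the highest-scoring 25%. This argues against 1 constant shift of the scores over these regions. Whether an overall scale accounts for the large arms stays open. For the smaller difference on chromosome 4 an overall shift or scale is argued against: 0 of 104 windows with at least 20 matched regions on the large arms, and 1 of all 121 windows, had a median difference as low. Lower scores of the regions there are also argued against: set against large-arm regions of the same score decile, the 92 regions on chromosome 4 and the scaffolds still fell short, with a median of -0.15 (two-sided permutation p = 5e-04, the smallest that 2000 resamples can give). Single regions were permuted, and neighbouring regions of 1 pair of libraries are not independent, so this p-value may be too small. The argument therefore rests on the size of the shortfall. A hypothesis is that the difference follows heterochromatin: the last 1 Mb at the centromere end had a lower median difference than the rest of its arm on 5 of 5 large arms (exact one-sided sign test p = 0.0312, two-sided 0.0625), by over 0.1 on 2L, 2R and 3L (0.06, 0.01 and 0.01, from only 19, 18 and 6 matched regions, against 0.19, 0.19 and 0.18) but hardly on 3R (0.188 against 0.193) and X (0.174 against 0.189). Against it stand XHet at 0.29 with 3 matched regions and U at 0.22 with 25, no lower than the large arms at 0.19; the pattern may reflect how the 2 libraries or their inputs recovered heterochromatin, which the region lists leave open, and no biological explanation was tested since both libraries belong to 1 group.

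Whether the regions found in only 1 replicate list were regions near the calling threshold stays open. In the replicate with the lower share, 97.4% of them were in the lowest-scoring 25% of their list, but this restates their low scores, and the threshold is not given in the sources used here. An arm handled differently in 1 of the lists is argued against as the cause of most of them, since no arm held more than 29.5% of the regions in only 1 list. A smaller part of this kind stays open, as 2L held 24 such regions in replicate 1 and 6 in replicate 2, and 3L held 22 and 23. A difference in depth between the libraries stays open, as depth is unknown.

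The greater width of regions on X was 76 bp, 2701 against 2625, among regions over 5 kb from both neighbours (window permutation p = 0.218). After matching by score, the mean over 10 score deciles of the difference of medians was 57.9 bp (permutation p = 0.37). Both values are below the 174 bp of all regions and above the 50 bp set beforehand as the limit for an explanation. The decile mean is another measure than the 174 bp, and width rose with score, so they are not directly comparable. The merging of close neighbours and the scores on X each stay open as partial causes, though the score difference did not pass the test in the combined list. X was not denser in regions than the autosomal arms, and merging neighbours within 500 bp gave 221 bp. Neither value decides on merging as a cause. Density was counted after any merging in the calling, and joining more neighbours cannot undo joins already made. No biological explanation was tested, since the labels do not give the sex of the larvae.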
